A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

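RNA from 8 yeast cultures was measured on 8 Affymetrix oligonucleotide arrays, with 2 arrays in each of 4 groups: ELF-MF sham, ELF-MF exposed, RF-EMF sham and RF-EMF exposed. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and made into biotinylated cRNA by the manufacturer's standard procedure. Per the submitters' processing notes, the software was GCOS 1.0. The algorithm and settings used in it are not given in the sources used here. The authors deposited 1 intensity for each probe set and array. These intensities were on a linear scale and all above 0, and their 2%-trimmed means lay between 500 and 501 on the 8 arrays, so each array had already been scaled to a common level. The deposited values carried no detection calls that could be used here, so a low intensity was not separated into present and absent.

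The arrays held 9335 probe sets, of which 60 were controls. A platform annotation gave 6504 probe sets 1 gene, 328 several genes and 2443 none; the last are unnamed here. All 6504 gene identifiers matched the reference annotation. Only probe sets with 1 gene were used, which gave 5656 genes. For the 315 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays was taken. Values were analysed as log2(intensity + 16). A fold change is therefore on that scale, which understates the change of weakly expressed genes. The 25% of genes with the lowest mean log2 value, below 6.79 (an intensity of 94.7), was left out, which removed 1414 genes and left 4242. Some probe sets recognise several near-identical sequences, among them those of ribosomal protein paralogs, tRNA families and the transporters HXT6 and HXT7, so the values of such genes are uncertain. Whether the labelling captured tRNA, snoRNA, snRNA and rRNA as it did mRNA was not examined. Values of such genes are therefore uncertain as transcript levels. No genomic coordinates were used, and genes are identified by symbol or locus name.

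Differences were tested in R 4.3.3 with limma 3.58.1, by lmFit and eBayes with a mean-variance trend, two-sided, in a single fit to all 8 arrays with a mean for each of the 4 groups. This fit had 4 residual degrees of freedom and a median of 16.6 prior degrees of freedom. The 4 comparisons were exposed minus sham for ELF-MF, exposed minus sham for RF-EMF, the RF-EMF effect minus the ELF-MF effect, and RF-EMF sham minus ELF-MF sham. Adjusted p-values are Benjamini-Hochberg values over the 4242 genes, with a threshold of 0.05. In total 28 gene lists were written down in advance, covering stress responses, ribosomes, energy metabolism, nutrient regulons, the cell surface, the cell cycle and mating type. The 26 lists with at least 3 tested genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists of a comparison. Camera with an estimated correlation and fry were the alternatives. In the sham comparison camera with an estimated correlation called 0 of 26 lists, although 67.2% of genes passed by limma. A call lost under it is therefore not evidence that a list was unchanged. Camera asks whether a list moves relative to the other genes, and fry whether its genes move, on balance, in 1 direction. Genes were also counted as separated when the exposed arrays both lay above or both lay below the sham arrays.

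The groups, the tests, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where stated. For each exposure the rule named the 10 genes with the largest change in each direction among those past the threshold, filled up with the genes of lowest unadjusted p whose arrays did not overlap. For the other comparisons it named 5 in each direction. It added up to 4 members with the largest change from each list that passed, 5 genes recalled as followed up by the study (SMC3, AQY2, HAL9, YAK1 and TOH1) and 4 auxotrophy genes that check the strain.

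The alternatives were quantile normalization, scaling to a common median, a pseudocount of 1 or 64, no filter or a stricter filter on low values, the mean of a gene's probe sets, all probe sets named or not, no mean-variance trend, only the arrays compared, the replicate number as a block, a fold of 2 for separated genes, and leaving out each array in turn. Restriction to protein-coding genes and leaving out both ELF-MF arrays with replicate number 1 were added after the data had been seen. Whether replicate numbers paired the arrays was checked by correlating, across genes, the differences between replicates of 2 groups. The 6 correlations ran from 0.0362 to 0.370, and 3 of them were below 0.1, so the numbers were not taken to pair the cultures.

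The procedure was tested on simulated data with 4242 genes, the moderated spread that limma fitted to each gene, 200 changed genes and 20 simulations. For the ELF-MF comparison it recovered 19.2% of genes changed 1.5-fold, 75.8% of those changed 2-fold and 99.5% of those changed 3-fold, with 7.95 false calls per simulation. For the RF-EMF comparison it recovered 17.9%, 77.3% and 100%, with 7.6 false calls per simulation. A list of 40 genes shifted by 0.3 on the log2 scale was called in 20 of 20 simulations for either exposure, and an unchanged list in 0 of 20 by camera with the preset correlation. Genes were simulated independently of each other there, so this says nothing about lists of co-regulated genes. The noise was normal and held no difference between replicate numbers, so the shares of genes recovered hold for that setting and may be too high for the real arrays. The number of arrays limits the precision of every value.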

Results

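Budding yeast was held for 6 h in an extremely low frequency magnetic field (ELF-MF) of 50 Hz and 0.4 mT, or in a radiofrequency electromagnetic field (RF-EMF) of 1800 MHz that deposited 3.5 W/kg of power in the sample. Each exposure had a sham group kept without the field. Cultures for ELF-MF were in 100 mm dishes and those for RF-EMF in 35 mm dishes. Transcript levels were measured on 8 arrays, 2 per group, as intensities scaled by the authors. The labels call the replicates biological and describe seeding of the dishes from 1 parental flask. The p-values therefore measure the spread between dishes together with differences between arrays, such as that by replicate number given below. Median intensity over 9335 probe sets was 138 to 146 on the ELF-MF arrays and 91.4 to 104 on the RF-EMF arrays, and 78.7% to 86.9% of values on an array lay above 16. Replicates correlated across genes at r = 0.97 to 0.98, while an ELF-MF and an RF-EMF array correlated at 0.50 to 0.57. The median gene had a standard error of 0.25 for a log2 fold change between 2 groups, which gives a 95% interval of 0.53 on either side. Of 3 kinds of control probe sets, 2 differed between replicate numbers within every group. Bacterial hybridisation spike-ins were higher on replicate 2 in 36 of 36 pairs, by a median of 1.57-fold to 1.94-fold per group. Ribosomal RNA controls were higher on replicate 2 in 37 of 40 pairs, by a median of 1.92-fold to 11.1-fold. Bacillus poly-A spike-ins were higher on replicate 2 in 29 of 48 pairs, with a median of 0.887-fold to 1.31-fold per group.

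The first comparison asked which transcripts differed after ELF-MF exposure. SNR14 (YNCE0011C), the U4 RNA of the spliceosome, gave an intensity of 311 ± 124 (SD, n = 2) on the exposed arrays and 1092 ± 535 (SD, n = 2) on the sham arrays. That is a log2 fold change of -1.72 (SE 0.33, adjusted p = 0.107). How far labelling rather than transcript level set the signal of this non-coding RNA was not tested. DBP2 (YNL112W), a DEAD-box RNA helicase, gave 340 ± 6.81 against 766 ± 69.6 (SD, n = 2 each), a log2 fold change of -1.13 (SE 0.22, adjusted p = 0.107). ADE17, an enzyme of purine synthesis, was at -1.04 (SE 0.23, adjusted p = 0.237). TIR1, a cell wall mannoprotein, was at -0.99, ARG1 of arginine synthesis at -0.90 and NSR1, a nucleolar protein of ribosome assembly, at -0.83 (adjusted p = 0.628 each). Further values below the sham arrays were -0.79 for GCV1 of the glycine cleavage system, -0.82 for the mitochondrial dicarboxylate carrier DIC1 and -0.72 for FRS2, a subunit of phenylalanyl-tRNA synthetase (adjusted p = 0.834 to 0.996). On the other side stood the tRNA gene YNCG0028W at 1.06 and DAL5, an allantoate permease, at 0.90 (adjusted p = 0.834 each). The snoRNA SNR73 (0.82), AIM2 (0.82), MDV1 of mitochondrial fission (0.75), the ATP synthase subunit ATP2 (0.73), ELF1, a transcription elongation factor (0.70), PMT7 (0.70), the siderophore transporter SIT1 (0.69) and YOR292C (0.69) all had an adjusted p of 0.996. Some of these values moved by more than 1.5 times when an array was left out: AIM2 to 0.32 and MDV1 to 0.37 without ELF-MF sham replicate 1, AIM2 to 1.31 and MDV1 to 1.14 without ELF-MF sham replicate 2, YNCG0028W to 0.67 and ELF1 to 0.43 without ELF-MF exposed replicate 1, and ATP2 to 0.41 without ELF-MF exposed replicate 2. SNR73 was at 0.52 with a pseudocount of 64.

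By limma, 0 of the 4242 genes passed the threshold for ELF-MF, and 189 (4.46%) had an unadjusted p under 0.05. SNR14 and DBP2 were nearest to it. SNR14 passed with ELF-MF sham replicate 2 left out (-2.24, adjusted p = 0.0115) or ELF-MF exposed replicate 1 left out (-2.12, adjusted p = 0.0131). With ELF-MF exposed replicate 1 left out, the ribosomal protein gene RPL7B, at -1.63 (adjusted p = 0.856) over all arrays, also passed (-2.87, adjusted p = 1.23e-05). Its low value rests on ELF-MF exposed replicate 2, with an intensity of 185 against 1110 on the other exposed array, and without that array it was -0.38 (adjusted p = 0.999). With the replicate number over all 8 arrays as a block, SNR14 (adjusted p = 0.000584) and DBP2 (adjusted p = 0.0428) passed. Both passed with the stricter filter on low values (adjusted p = 0.0376 each), SNR14 with only the ELF-MF arrays fitted (adjusted p = 0.0235) and DBP2 with the mean of its probe sets (adjusted p = 0.0360). In total SNR14 passed in 6 of 19 alternatives and DBP2 in 3, against an adjusted p of up to 0.9998 for either in the others. The exposed and sham arrays were separated for 1345 genes (31.7%), where chance gives 33.3%. Of these, 113 differed at least 1.5-fold, 40 higher and 73 lower on the exposed arrays. The split of the same 4 arrays by replicate number gave 213 such genes, and the remaining split gave 69. Leaving out an array loosens the criterion, and the count was then 470 without ELF-MF sham replicate 2, 329 without ELF-MF exposed replicate 1 and 301 without ELF-MF exposed replicate 2.

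**Figure D1:**
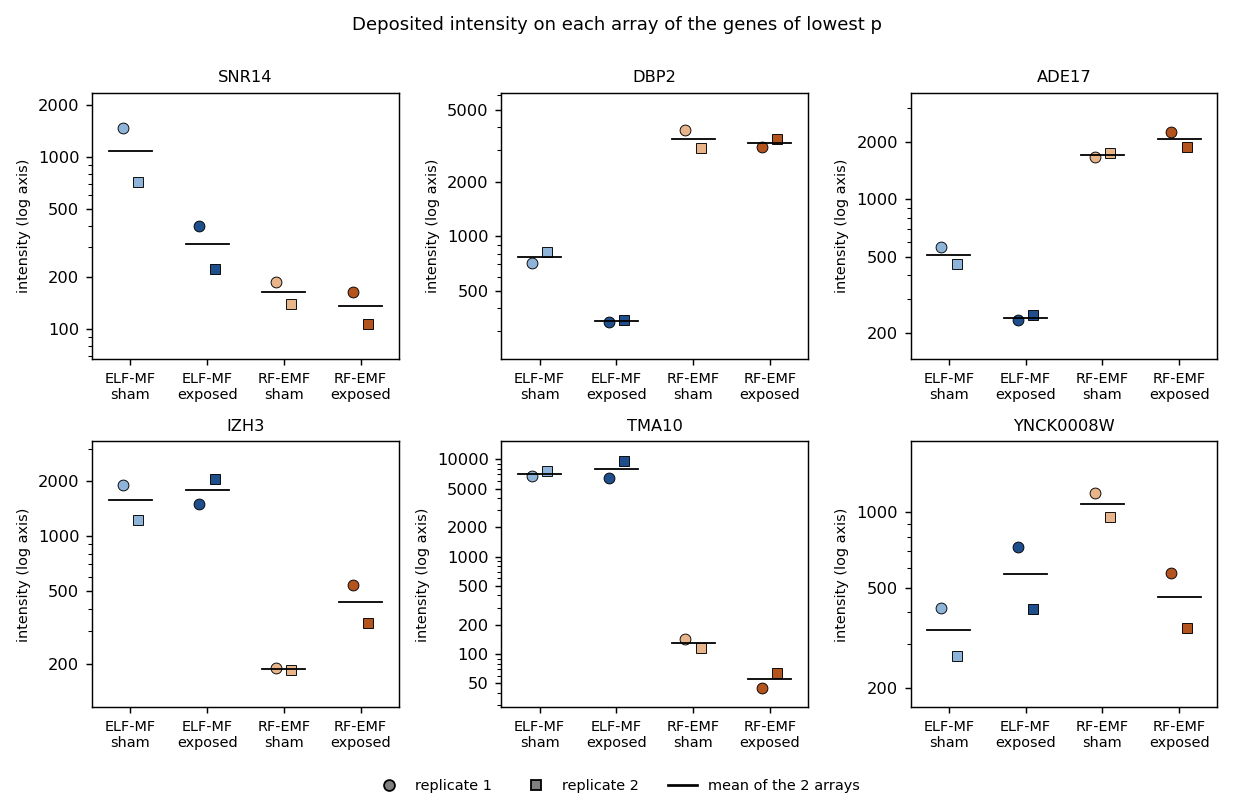
Deposited intensity (log axis) of 6 genes with low p-values on each of the 8 arrays, by group, with a circle for replicate 1, a square for replicate 2 and a line at the mean of the 2 arrays. SNR14, DBP2 and ADE17 lay lower on both ELF-MF exposed arrays than on both ELF-MF sham arrays, IZH3 lay higher and TMA10 and YNCK0008W lower on both RF-EMF exposed arrays than on both RF-EMF sham arrays, and no adjusted p was below 0.107.

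Among the gene lists under ELF-MF, genes of cytosolic ribosomal proteins fell as a set, by a median of -0.29 (SD over genes 0.25). Of 80 tested members 73 were lower and 7 higher on the exposed arrays, and 0 passed on their own (limma). RPL31B was at -0.72, RPL24A at -0.70 and RPS9A at -0.68. The call came from camera with its preset correlation (adjusted p = 7.99e-12) and was lost (adjusted p = 0.705 with an estimated correlation). Without ELF-MF exposed replicate 2 the median was -0.18, RPL24A was at -0.43 and RPS9A at -0.37. Ribosome biogenesis genes fell by a median of -0.19, with 29 of 38 lower, among them NMD3, an export factor of the large subunit, at -0.84 and RRP12 at -0.70 (adjusted p = 0.00019, and adjusted p = 0.637 with an estimated correlation). The array medians of this list overlapped, at 8.35 and 7.94 on the sham arrays against 8.15 and 7.92 on the exposed arrays. Genes of the TCA cycle and respiratory chain rose by a median of 0.21, with 36 of 40 higher (adjusted p = 1.52e-07, and adjusted p = 0.637 with an estimated correlation). Complex III subunit COR1 was at 0.63, ATP synthase subunit ATP5 at 0.58 and aconitase ACO1 at 0.54. This call was lost without ELF-MF exposed replicate 2 (median 0.14, adjusted p = 0.0936). NMD3 was at -0.54 without ELF-MF sham replicate 1 and -0.55 without ELF-MF exposed replicate 2. COR1 was at 0.28 and 0.97 without ELF-MF sham replicates 1 and 2 and at 0.38 without ELF-MF exposed replicate 2, ATP5 at 0.28 and 0.87 without ELF-MF exposed replicates 1 and 2, and ACO1 at 0.31 without ELF-MF sham replicate 2. Control probe sets also differed between the ELF-MF exposed and sham arrays by amounts of the size of these list medians. Ribosomal RNA controls had a median of -0.54 (9 of 10 lower) and bacterial hybridisation spike-ins 0.38 (9 of 9 higher), each with array medians that overlapped between the groups, and Bacillus poly-A spike-ins 0.23 (11 of 12 higher).

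Cell wall genes fell by a median of -0.21, with 20 of 24 lower (adjusted p = 0.00373, and adjusted p = 0.637 with an estimated correlation). EGT2 was at -0.69, the structural wall protein PIR1 at -0.61, the glucan synthase subunit GSC2 at -0.60 and the chitin synthase CHS2 at -0.42. The call was lost without ELF-MF sham replicate 2 (adjusted p = 0.219) or ELF-MF exposed replicate 1 (adjusted p = 0.686), with the mean of a gene's probe sets (adjusted p = 0.0517) and over all probe sets (median -0.06, adjusted p = 0.901). Ergosterol genes fell by a median of -0.18, with 19 of 23 lower (adjusted p = 0.0215, and adjusted p = 0.705 with an estimated correlation). Their array medians overlapped, at 9.64 and 9.24 on the sham arrays against 9.29 and 8.91 on the exposed arrays. The squalene epoxidase ERG1 was at -0.60, ERG26 at -0.52, the HMG-CoA reductase HMG1 at -0.41 and ERG11 at -0.36. The call was lost without ELF-MF sham replicate 1 (median -0.05, adjusted p = 0.230) or ELF-MF exposed replicate 2 (median -0.12, adjusted p = 0.161), and the median was -0.34 without ELF-MF sham replicate 2 and -0.29 without ELF-MF exposed replicate 1. MATa-specific and pheromone response genes rose by a median of 0.26, with 10 of 13 higher (adjusted p = 0.00376, and adjusted p = 0.637 with an estimated correlation). PRM1 was at 0.58, the a-factor exporter STE6 at 0.49, ASG7 at 0.45 and FUS1 of cell fusion at 0.40. This call was lost without ELF-MF sham replicate 2 (median 0.17, adjusted p = 0.0729) and with the stricter filter (adjusted p = 0.0927). Single members moved too. Without ELF-MF exposed replicate 1, CHS2 was at -0.17, HMG1 at -0.12, STE6 at 0.75 and ASG7 at 0.26. Without ELF-MF exposed replicate 2, CHS2 was at -0.67, HMG1 at -0.69, STE6 at 0.23 and PRM1 at 0.34. HMG1 was at -0.25 without ELF-MF sham replicate 1, and CHS2 at -0.27 with a pseudocount of 64. Without both number-1 ELF-MF arrays, a setting chosen after seeing the data, the cell wall (adjusted p = 0.288) and ergosterol (median -0.15, adjusted p = 0.206) calls were lost and the MATa median was 0.16 (adjusted p = 0.0112).

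Camera with the preset correlation thus called 6 of 26 lists for ELF-MF, 2 higher and 4 lower. With an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05, and fry called 0, with 0 lists at an unadjusted p under 0.05. Among the lists that did not pass, glucose-repressed and gluconeogenic genes had the lowest adjusted p (0.0648, median 0.14). Heat shock proteins and chaperones had a median of 0.02 (adjusted p = 0.956), oxidative stress defence genes 0.02 (adjusted p = 0.698) and DNA damage genes -0.06 (adjusted p = 0.837). Adjusted over the list alone, 2 members of the ribosome biogenesis list, 1 of the amino acid biosynthesis list and 1 of the anaerobic list passed, against 0 over all genes.

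**Figure D2:**
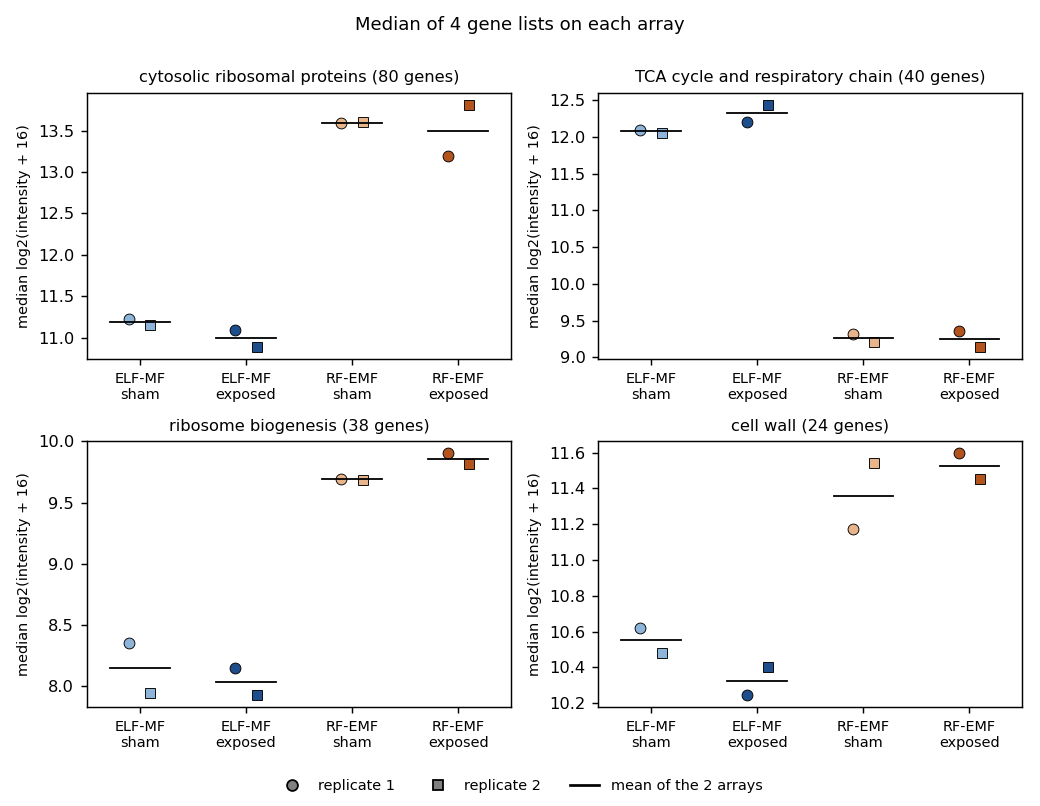
Median log2(intensity + 16) of the tested genes of 4 lists on each array, by group, with a circle for replicate 1, a square for replicate 2 and a line at the mean of the 2 arrays. Ribosomal protein medians were 11.23 and 11.15 on the ELF-MF sham arrays against 11.10 and 10.88 on the exposed arrays, while the RF-EMF exposed arrays, at 13.19 and 13.81, lay on either side of their sham arrays.

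The RF-EMF comparison asked the same of the radiofrequency field. IZH3, a membrane protein of zinc homeostasis, gave 437 ± 148 on the exposed arrays and 186 ± 2.99 on the sham arrays (SD, n = 2 each), a log2 fold change of 1.12 (SE 0.27, adjusted p = 0.722). By unadjusted p the next genes on the higher side included RPM2, the protein of mitochondrial RNase P, at 0.92, LAT1 of the pyruvate dehydrogenase complex at 0.91 and the ATP synthase subunit ATP3 at 0.77. The rest of the 10 named by the rule on this side were FBP26, a fructose-2,6-bisphosphatase (0.89), GPT2 of phospholipid synthesis (0.84), ATG11 of selective autophagy (0.83), ECM21, an arrestin-related protein (0.82), YMR114C (0.80) and the kinase YPK1 (0.73), with an adjusted p of 0.892 each. The genes named on the lower side began with TMA10, a ribosome-associated protein, at -1.04 (SE 0.25, adjusted p = 0.722; 55.0 ± 13.6 against 129 ± 17.7, SD, n = 2 each) and the tRNA gene YNCK0008W at -1.24 (SE 0.30, adjusted p = 0.722). A further 6 of the 10 named by the rule on this side were tRNA genes: YNCK0019W (-1.0), YNCD0004W (-0.97), YNCP0022W (-0.97), YNCL0035C (-0.94), YNCM0018C (-0.87) and YNCJ0005C (-0.85). The last were ROQ1 at -0.94 and BNS1 at -0.81, all with an adjusted p of 0.892. The median over all tested genes was 0.12, and 0.04 under quantile normalization and -0.02 under median scaling, so these fold changes include a shift of the whole distribution. With an array left out, LAT1 was at 0.57, ROQ1 at -0.63 and YNCM0018C at -0.57 without RF-EMF sham replicate 1, and RPM2 was at 0.58 and ROQ1 at -0.55 without RF-EMF exposed replicate 2. With a pseudocount of 64, RPM2 was at 0.48, ATG11 at 0.53, YMR114C at 0.33, BNS1 at -0.48 and ROQ1 at -0.54.

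By limma, 0 of 4242 genes passed for RF-EMF, and 219 (5.16%) had an unadjusted p under 0.05. With the replicate number over all 8 arrays as a block, YNCK0008W passed (adjusted p = 0.0358, against up to 0.986 in the other alternatives). Without RF-EMF sham replicate 2 the count was 1, the mitochondrial pyruvate carrier gene MPC3 (-2.37, adjusted p = 0.00079), a gene named here only after its value was seen. MPC3 was at -1.20 over all arrays, -0.03 without RF-EMF sham replicate 1 and -0.70 without RF-EMF exposed replicate 2. Exposed and sham arrays were separated for 1593 genes (37.6%), where chance gives 33.3%. Of these, 139 differed at least 1.5-fold, 97 higher and 42 lower, against 155 for the split by replicate number and 102 for the remaining split. The count was 249 and 420 without RF-EMF sham replicates 1 and 2, and 250 and 425 without RF-EMF exposed replicates 1 and 2.

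The 5 genes recalled as followed up by the study were each higher on the RF-EMF exposed arrays, as were 2846 of all 4132 tested protein-coding genes. By limma 0 of the 5 genes passed (adjusted p = 0.892 each). SMC3, a cohesin subunit, was at 0.48 (SE 0.23), the aquaporin gene AQY2 at 0.49 (SE 0.25), HAL9, a transcription factor of salt tolerance, at 0.42 (SE 0.26), the kinase YAK1 at 0.62 (SE 0.24) and the cell wall protein TOH1 (YJL171C) at 0.65 (SE 0.27). They had been chosen on these arrays, so their direction is not independent evidence, and 3 of them, SMC3, YAK1 and TOH1, had an unadjusted p under 0.05. Under ELF-MF the same genes were at -0.0012 (SMC3), 0.29 (AQY2), -0.29 (HAL9), 0.33 (YAK1) and 0.41 (TOH1), with adjusted p-values of 0.996 or above. SMC3 turned to 0.07 without ELF-MF sham replicate 2 and to 0.06 without ELF-MF exposed replicate 2, and HAL9 turned to 0.02 without ELF-MF exposed replicate 1 and was at -0.60 without ELF-MF exposed replicate 2. Under RF-EMF, AQY2 was at 0.26 and TOH1 at 0.43 without RF-EMF sham replicate 1, HAL9 at 0.25 and TOH1 at 0.30 without RF-EMF exposed replicate 1, and TOH1 at 0.999 without RF-EMF exposed replicate 2. HAL9 was at 0.27 under quantile normalization.

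Ribosomal protein genes were the single list called for RF-EMF. Their median fell by 0.12, or by 0.24 relative to the median of all genes, with 68 of 80 members lower and 0 past the threshold on their own by limma or adjusted over the list alone (adjusted p = 8.74e-10, and adjusted p = 0.715 with an estimated correlation). RPS20 was at -0.63, RPL15B and RPL29 at -0.42 and RPS26B at -0.40. Without RF-EMF exposed replicate 1 the median turned to 0.14 (adjusted p = 0.220), and it was -0.21 without RF-EMF sham replicate 1 and -0.42 without RF-EMF exposed replicate 2. Under quantile normalization it was -0.0093 (adjusted p = 0.497), and under median scaling -0.26. RPL15B was at -0.66 and -0.18 without RF-EMF sham replicates 1 and 2, RPL29 at -0.10 and -0.73 without RF-EMF exposed replicates 1 and 2 and at -0.26 under quantile normalization, and RPS20 at -0.41 without RF-EMF exposed replicate 2 and at -0.38 under quantile normalization. Methionine and sulfur assimilation genes had a median of 0.31, with 15 of 18 higher (adjusted p = 0.121), and DNA damage genes a median of 0.27, with 10 of 11 higher (adjusted p = 0.0817). Amino acid biosynthesis genes stood at 0.21, with 37 of 42 higher (adjusted p = 0.131), heat shock proteins and chaperones at 0.09 (adjusted p = 0.846) and salt tolerance genes at 0.19 (adjusted p = 0.262). Of all 4132 tested protein-coding genes 2846 were higher, so counts of higher members lean upward without a list effect. With an estimated correlation camera called 0 lists, with 0 at an unadjusted p under 0.05. Fry also called 0 lists, with 2 at an unadjusted p under 0.05. The preset correlation gave 3 lists under quantile normalization and without RF-EMF exposed replicate 2, 2 lists over all probe sets and without RF-EMF sham replicate 1, and 0 without RF-EMF exposed replicate 1. Between RF-EMF exposed and sham arrays the median was 0.37 for Bacillus spike-ins (10 of 12 higher), -0.22 for ribosomal RNA controls (8 of 10 lower) and -0.08 for bacterial spike-ins (7 of 9 lower).

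The difference of the effects was taken as the RF-EMF effect minus the ELF-MF effect, so that a positive value means a higher value in the RF-EMF comparison. The fields were applied in different dishes and exposure systems, to cultures whose sham groups differed in 2850 of 4242 genes by limma. A difference between the fields therefore cannot be told apart from a difference between the cultures. ADE17 was at 1.31 (SE 0.32) and the acid phosphatase PHO3 at 1.50 (SE 0.38), with an adjusted p of 0.431 each. ATG11 at 1.17 and DBP2 at 1.06 had an adjusted p of 0.760, and SHM2, the cytosolic serine hydroxymethyltransferase, at 1.06 one of 0.804. At the other end stood the tRNA genes YNCK0008W (-1.93, SE 0.42), YNCK0019W (-1.68), YNCD0004W (-1.53) and YNCJ0005C (-1.35) and the spliceosomal U6 RNA SNR6 (-1.51), with an adjusted p of 0.431 each. By limma 0 of 4242 genes passed, and 182 (4.29%) had an unadjusted p under 0.05. With the replicate number over all 8 arrays as a block YNCK0008W passed (adjusted p = 0.00882). Without ELF-MF exposed replicate 2 both YNCK0008W (-2.33) and YNCK0019W (-2.12) passed (adjusted p = 0.0386 each), and without ELF-MF exposed replicate 1 RPL7B did (2.89, adjusted p = 0.00112, against 1.65 over all arrays and 0.40 without ELF-MF exposed replicate 2). The all-gene median of this difference was 0.14, 0.05 under quantile normalization and -0.05 under median scaling.

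Camera with the preset correlation called 7 lists for this difference. Counts of positive members have to be read against 2823 of 4132 protein-coding genes that were positive. Cell wall genes (median 0.36, 23 of 24 positive, adjusted p = 0.00642), ergosterol genes (0.34, 22 of 23 positive, adjusted p = 0.0102), ribosome biogenesis genes (0.31, 34 of 38 positive, adjusted p = 0.00642) and phosphate regulon genes (0.26, 12 of 15 positive, adjusted p = 0.018) were higher in the RF-EMF than in the ELF-MF comparison. MATa-specific and pheromone response genes (-0.24, 10 of 13 negative, adjusted p = 0.00642), glucose-repressed and gluconeogenic genes (-0.19, 15 of 18 negative, adjusted p = 0.00903) and TCA cycle and respiratory chain genes (-0.12, 28 of 40 negative, adjusted p = 0.00642) were lower. Each of the 7 was lost (adjusted p = 0.617 with an estimated correlation). Under median scaling the medians were 0.17, 0.16, 0.12 and 0.07 for the first 4 lists and -0.43, -0.38 and -0.31 for the other 3, in the same order, and that of the TCA cycle list was -0.24 under quantile normalization. Over all probe sets the cell wall (adjusted p = 0.0532) and gluconeogenic (adjusted p = 0.0863) calls were lost, and with the stricter filter the phosphate call was (adjusted p = 0.0933). Members with large differences were EGT2 (1.06), GSC2 (0.92), CHS2 (0.90) and SCW10 (0.72) of the cell wall, HMG1 (0.72) and ERG5 (0.67) of sterol synthesis, NSR1 (0.92), NOP1 (0.89) and RPA190 (0.87) of ribosome biogenesis, and PHM6 (0.81) and PHO5 (0.72) of the phosphate regulon. The pheromone gene MFA1 was at -0.61, MLS1 of the glyoxylate cycle at -0.52 and COR1 at -0.91, whereas ADH2 (0.59) and ATP3 (0.65) went against their lists, and POT1 moved from -0.44 to 0.04 without RF-EMF sham replicate 2, and to -0.01 without RF-EMF exposed replicate 1. It was -0.91 and -0.86 without RF-EMF sham replicate 1 and RF-EMF exposed replicate 2, and -0.80 and -0.27 with a pseudocount of 1 and 64. NOP1 was at 1.45 and 0.32 without ELF-MF exposed replicates 1 and 2, CHS2 at 0.57 without RF-EMF sham replicate 2, HMG1 at 0.43 without ELF-MF exposed replicate 1, and ERG5 at 0.44 and COR1 at -0.57 without ELF-MF sham replicate 1. PHM6 was at 0.48 and ADH2 at 0.38 without ELF-MF exposed replicate 2, ADH2 at 0.32 and MLS1 at -0.33 without RF-EMF exposed replicate 2, and MLS1 at -0.79 and -0.25 without RF-EMF sham replicates 1 and 2. MLS1 was at -0.34 with a pseudocount of 64, and with the mean of a gene's probe sets SCW10 was at 0.32 and MFA1 at -0.36. Over the phosphate list alone 1 gene passed, and 0 did in the other 6 lists or over all genes. Across the 4242 genes the fold changes for ELF-MF and RF-EMF correlated at r = 0.0951 (Spearman 0.119), 1 relation computed over genes, which are not independent replicates. This r was 0.154 without ELF-MF exposed replicate 1, -0.0019 without ELF-MF exposed replicate 2, 0.0599 without ELF-MF sham replicate 2 and 0.0591 without a filter, so its size and sign rest on single arrays.

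Each of these 7 calls also ended when single arrays were left out. The count of lists was 3 of 26 without ELF-MF sham replicate 1, 4 without ELF-MF sham replicate 2, 1 without ELF-MF exposed replicate 2 and 4 without RF-EMF sham replicate 1. In what follows the brackets give the adjusted p without the array. Ribosome biogenesis genes were lost without ELF-MF exposed replicate 2 (0.104) or RF-EMF sham replicate 2 (0.0902). Cell wall genes were lost without ELF-MF sham replicate 2 (0.0777), ELF-MF exposed replicate 1 (0.259), RF-EMF sham replicate 1 (median 0.24, 0.153), RF-EMF exposed replicate 2 (0.0591) or both number-1 ELF-MF arrays (0.0881). Ergosterol genes were lost without ELF-MF sham replicate 1 (0.109), ELF-MF exposed replicate 2 (0.112), RF-EMF sham replicate 1 (0.188) or RF-EMF exposed replicate 1 (0.0506). Phosphate genes were lost in 5 of the 8 cases, at 0.0649 and 0.0542 without ELF-MF sham replicates 1 and 2 (median 0.39 without the latter), 0.104 without ELF-MF exposed replicate 2 (median 0.43), 0.0982 without RF-EMF sham replicate 2 and 0.0978 without RF-EMF exposed replicate 2. MATa genes were lost without ELF-MF sham replicate 2 (0.0508), ELF-MF exposed replicate 2 (0.104) or RF-EMF sham replicate 1 (median -0.02, 0.153), and their median was -0.44 without RF-EMF sham replicate 2 and -0.15 without RF-EMF exposed replicate 2. Gluconeogenic genes were lost without ELF-MF sham replicate 1 (0.153), ELF-MF exposed replicate 2 (0.224) or RF-EMF exposed replicate 1 (median -0.06, 0.402). TCA cycle genes were lost without ELF-MF sham replicate 1 (0.109), ELF-MF exposed replicate 2 (median -0.01, 0.362) or RF-EMF sham replicate 1 (median -0.07, 0.109), and their median was -0.23 without ELF-MF exposed replicate 1, -0.20 without RF-EMF exposed replicate 1 and -0.0029 without RF-EMF exposed replicate 2.

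Genes of tRNAs are described here as a class that was singled out only after its values had been seen. Their median was 0.26 for ELF-MF, with 66 of 67 genes higher on the exposed arrays, and -0.63 for RF-EMF, with 65 of 67 lower. The difference of the effects had a median of -0.84 and was negative for 67 of 67. By limma 0 of the 67 genes passed in any of these 3 comparisons. Other non-coding classes, with 0 genes past the threshold, partly moved the same way. Of 31 snoRNA genes 24 were higher for ELF-MF (median 0.17) and 21 lower for RF-EMF (median -0.06), and the difference was negative for 24. The 4 snRNA and 4 rRNA genes were each lower for RF-EMF (medians -0.37 and -0.34), but had negative medians for ELF-MF as well (-0.31 and -0.32). Medians were 0.28, -0.65 and -0.87 under quantile normalization and 0.31, -0.76 and -1.03 under median scaling. Camera with an estimated correlation of 0.652 between these genes gave an unadjusted p of 0.233 for ELF-MF, 0.0363 for RF-EMF and 0.0281 for the difference. Of the 67 probe sets, 66 have a name suffix other than the plain form and may recognise more than 1 sequence. The kinds of suffix were not told apart.

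**Figure D3:**
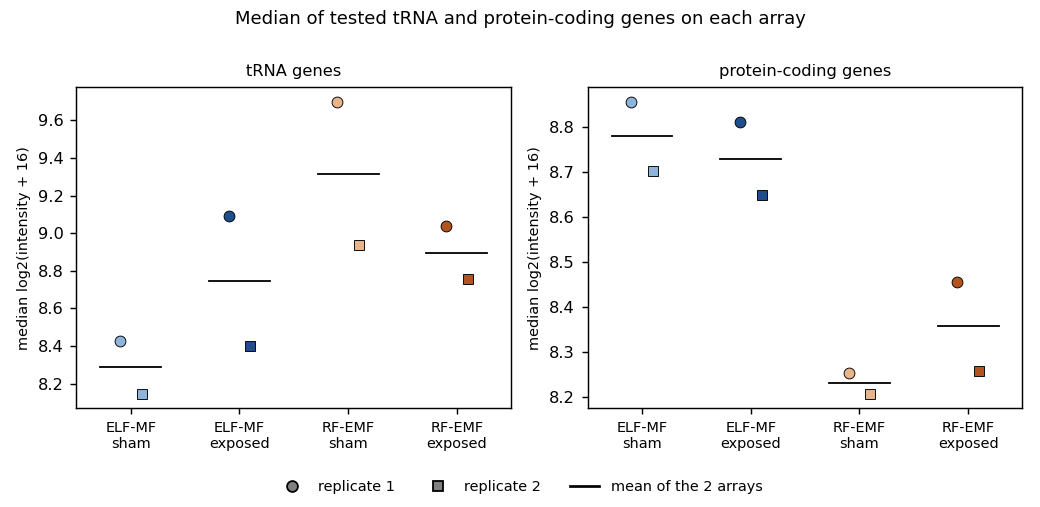
Median log2(intensity + 16) of the 67 tested tRNA genes and of the 4132 tested protein-coding genes on each array, by group, with a circle for replicate 1, a square for replicate 2 and a line at the mean of the 2 arrays. The tRNA medians were 8.43 and 8.15 on the ELF-MF sham arrays against 9.09 and 8.40 on the exposed arrays, and 9.70 and 8.94 on the RF-EMF sham arrays against 9.04 and 8.76, so the groups overlapped and replicate 1 lay above replicate 2 in each group.

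The last comparison set the sham groups against each other, as the background against which each exposure was measured. Relative to the ELF-MF sham arrays, the RF-EMF sham arrays gave a higher signal for HXT1, a low-affinity glucose transporter (1940 ± 121 against 67.8 ± 13.8, SD, n = 2 each), which rose by 4.55 (SE 0.25, adjusted p = 2.43e-12). The chaperone gene SSA2 rose by 4.24, the hypoxic translation factor gene ANB1 by 3.92, the ribosomal protein gene RPL9A by 3.87 and the tRNA gene YNCJ0008W by 3.60. In the other direction the membrane-protective heat shock gene HSP12 gave 23.8 ± 11.8 against 19277 ± 3338 (SD, n = 2 each) and fell, with a log2 fold change of -8.94 (adjusted p = 1.06e-15). Also lower were SPG4, a gene of stationary phase survival, at -8.86, RGI2 of respiratory growth at -8.07, the acetate transporter gene ATO2 at -7.45 and the lactate permease gene JEN1 at -7.22. On the RF-EMF sham arrays these 5 genes had intensities of 1.54 to 32.2, near or below the pseudocount of 16, so the size and order of these fold changes depend on the pseudocount. Over the alternatives they ran from -9.68 to -7.78 for HSP12, -10.35 to -7.37 for SPG4, -9.89 to -6.38 for RGI2, -8.21 to -6.25 for ATO2 and -9.87 to -5.36 for JEN1. The same holds for YNCJ0008W, low on the ELF-MF sham arrays (18.4 and 36.5), which ran from 2.63 to 4.21. By limma 2850 of 4242 genes (67.2%) passed, 1129 higher and 1721 lower on the RF-EMF sham arrays, of which 736 differed more than 4-fold. The share of higher calls was 39.6% as deposited, 55.3% under quantile normalization (1579 higher, 1274 lower) and 60.0% under median scaling (1736 higher, 1158 lower). The all-gene median moved from -0.26 to 0.16 and 0.28, so values near 0 have no settled direction.

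Of 27 general stress genes 27 fell and 0 rose, with a list median of -4.51 (adjusted p = 1.91e-14, and adjusted p = 0.160 with an estimated correlation). DDR2 was at -7.02, SOL4 at -6.89 and SPI1 at -6.56. Among 29 heat shock proteins and chaperones 21 fell, 5 rose and 3 did not pass (median -1.41, adjusted p = 0.00289, and adjusted p = 0.241 with an estimated correlation), with HSP30 at -6.99, HSP26 at -6.22 and HSP42 at -5.37. Glucose-repressed and gluconeogenic genes fell in 17 of 18 cases (median -4.82, adjusted p = 1.04e-09, and adjusted p = 0.160 with an estimated correlation), among them PCK1 (-6.69), FBP1 (-6.39) and MLS1 (-6.38). The sizes for SOL4, FBP1 and MLS1 also depend on the pseudocount, with RF-EMF sham intensities of 15.9 to 63.6, and ran from -7.33 to -6.04, -7.12 to -5.22 and -7.12 to -5.23. TCA cycle and respiratory chain genes fell in 38 of 40 cases (median -2.75, adjusted p = 7.82e-13, and adjusted p = 0.195 with an estimated correlation), among them the NADH dehydrogenase NDI1 (-4.64), QCR10 (-4.60), SDH2 (-4.56) and RIP1 (-3.84). Of 18 methionine and sulfur genes 12 fell and 1 rose (median -1.34, adjusted p = 0.044, and adjusted p = 0.337 with an estimated correlation), with STR3 at -3.41, MET30 at -3.14, MET2 at -3.12 and STR2 at -2.81. That call was lost under quantile normalization (median -0.83, adjusted p = 0.0749), with the stricter filter (adjusted p = 0.262), without RF-EMF sham replicate 1 (adjusted p = 0.0503), without RF-EMF sham replicate 2 (adjusted p = 0.0528), with a pseudocount of 64 (adjusted p = 0.0538), with the replicate number as a block within each exposure system (adjusted p = 0.0519) and with protein-coding genes only, a setting chosen after seeing the data (adjusted p = 0.0520).

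Cytosolic ribosomal protein genes rose in 79 of 80 cases (median 2.25, adjusted p = 1.33e-30, and adjusted p = 0.308 with an estimated correlation), among them RPS9B (3.41), RPL22A (3.38) and RPS7A (3.13). Ribosome biogenesis genes rose in 33 of 38 cases (median 1.37, adjusted p = 8.04e-12, and adjusted p = 0.179 with an estimated correlation), with the RNA polymerase I subunits RPA190 (2.74) and RPA135 (2.53) and the nucleolar proteins NOP1 (2.65) and NOP58 (2.41). In glycolysis and fermentation 12 of 16 genes rose and 1 fell (median 1.31, adjusted p = 0.000432, and adjusted p = 0.353 with an estimated correlation). PGK1 was at 2.55, PDC1 at 2.48 and ENO2 at 1.66 (0.78 under quantile normalization), against -2.70 for TDH1, an isoform of glyceraldehyde-3-phosphate dehydrogenase, and the list was lost under quantile normalization (median 0.57, adjusted p = 0.141). Amino acid biosynthesis genes rose in 26 of 42 cases and fell in 9 (median 1.07, adjusted p = 8.11e-05, and adjusted p = 0.297 with an estimated correlation), with ARO4 at 2.68, HIS1 at 2.35, THR1 at 2.17 and CPA1 at -2.60. Ergosterol genes rose in 14 of 23 cases and fell in 2 (median 0.93, adjusted p = 0.000432, and adjusted p = 0.337 with an estimated correlation), with ERG10 at 2.53, ERG4 at 1.96 and ERG9 at -1.49 (-0.95 under median scaling). Phosphate genes rose in 10 of 15 cases and fell in 4 (median 1.34, adjusted p = 0.0215, and adjusted p = 0.308 with an estimated correlation), with PHO5 at 2.43 and VTC3 at 2.37 against PHO89 at -3.47 and PHM8 at -2.57. Iron regulon genes rose in 12 of 25 cases and fell in 5 (median 0.52, adjusted p = 0.0398, and adjusted p = 0.337 with an estimated correlation), with FIT1 at 3.27 and FRE1 at 2.52 against HMX1 at -2.42 and AFT2 at -2.19.

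Under median scaling the median was 1.6 for amino acid genes, 1.47 for ergosterol genes, -0.87 for heat shock genes and -0.80 for methionine genes. The phosphate call was lost under quantile normalization (median 1.47, adjusted p = 0.0903) and median scaling (median 1.88, adjusted p = 0.0616). The iron call was lost under both, while its median was larger there than as deposited (0.84, adjusted p = 0.0977, and 1.06, adjusted p = 0.0507), with the stricter filter (median 0.56, adjusted p = 0.164) and without RF-EMF sham replicate 2 (median 0.47, adjusted p = 0.0761). Under these 2 scalings the all-gene median was higher too. Camera thus called 12 lists with the preset correlation and 0 with an estimated one, where 5 had an unadjusted p under 0.05, and fry called 19. Adjusted over the list alone, the genes that passed numbered 27 for general stress, 26 for heat shock, 17 for gluconeogenesis, 38 for the TCA cycle and respiration, 13 for methionine, 80 for ribosomal proteins, 35 for ribosome biogenesis, 13 for glycolysis, 36 for amino acids, 17 for ergosterol, 14 for phosphate and 17 for iron. Bacillus spike-in controls were 2.60-fold higher on the ELF-MF sham than on the RF-EMF sham arrays by median. Dish size and exposure system changed together between these groups, and the values of the groups do not separate them, so their parts cannot be told apart.

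**Figure D4:**
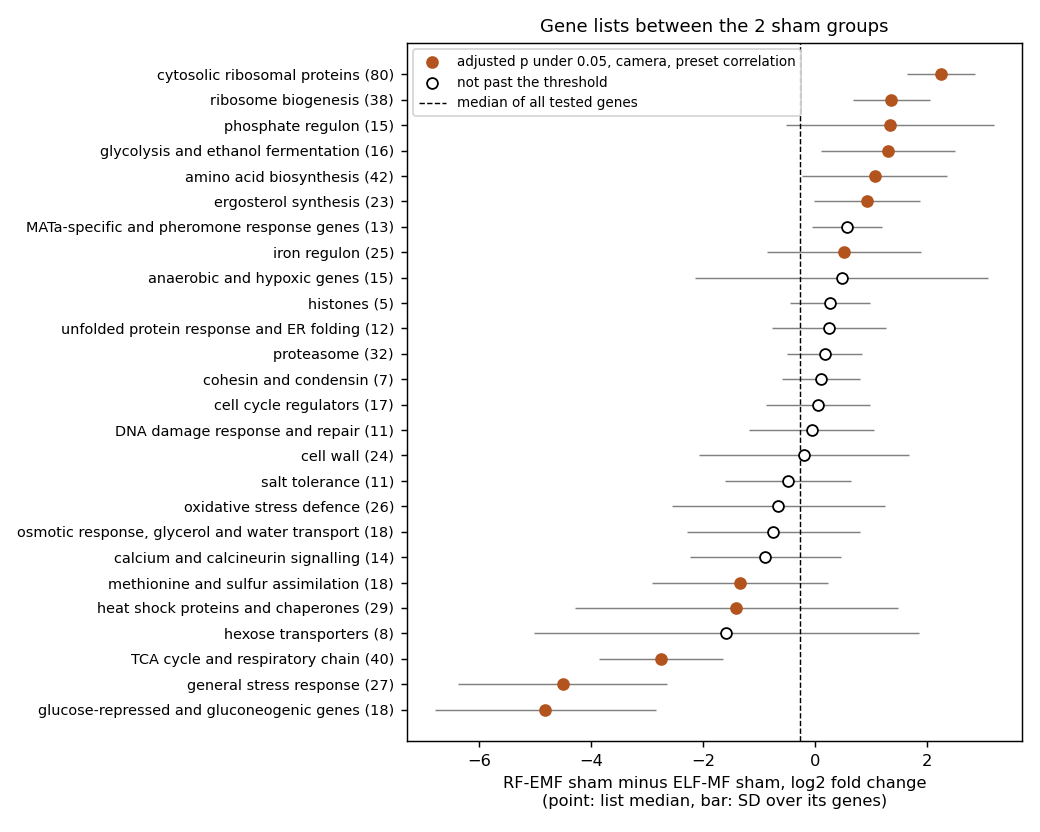
Median log2 fold change of 26 gene lists, RF-EMF sham minus ELF-MF sham, with bars for the SD over the genes of a list, the number of tested genes in brackets, filled points for lists past the threshold with the preset correlation and a dashed line at the all-gene median of -0.26. Gluconeogenic (-4.82) and general stress (-4.51) genes lay lowest and ribosomal protein genes (2.25) highest.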

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

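In this part, the test of shared array-to-array variation, the simulation without an effect and the comparison of replicates along the sham difference were chosen only after results had been seen. For 7 gene lists the effects of RF-EMF and ELF-MF differed by a test of the difference itself, camera with the preset correlation, and for all 7 that call was lost with an estimated correlation. The median of the RF-EMF effect minus the ELF-MF effect was 0.36 for cell wall genes, 0.34 for ergosterol genes, 0.31 for ribosome biogenesis genes and 0.26 for phosphate regulon genes. It was -0.24 for MATa-specific and pheromone response genes, -0.19 for glucose-repressed and gluconeogenic genes and -0.12 for TCA cycle and respiratory chain genes, against an all-gene median of 0.14.

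Under ELF-MF, ribosomal protein genes were lower (median -0.29) and TCA cycle and respiratory genes higher (median 0.21). A difference between arrays that depends on intensity alone is argued against, since the ribosomal protein median lay at percentile 0 and the respiratory median at percentile 100 of 10000 random lists matched on intensity. Array-to-array variation shared by co-regulated genes stays open: camera with an estimated correlation gave an unadjusted p of 0.230 for the ribosomal proteins and 0.0653 for the respiratory list. By that test 1 of 26 lists had an unadjusted p under 0.05 for ELF-MF, and 5 of 26 did between the sham groups. After adjustment it called 0 of 26 lists between the sham groups, even general stress genes with a median of -4.51 (adjusted p = 0.160). How often it would find a list shift of the ELF-MF size with so few arrays was not measured, so it does not decide the question. A small difference in growth state between dishes also stays open: with the difference between replicate numbers removed, over the 4122 genes outside both lists, ELF-MF exposed minus ELF-MF sham replicate 1 correlated with RF-EMF sham minus ELF-MF sham replicate 2 at r = -0.178, and at -0.211 with the ELF-MF sham arrays exchanged. In 100 simulations without an ELF-MF effect and with noise independent between genes r was -0.0268 to 0.0670. With the number left in, replicate 2 minus replicate 1 correlated with the sham difference at -0.102 (ELF-MF exposed) to -0.0104 (RF-EMF exposed). With the number removed the range was -0.0739 to 0.0518, where values on both sides of 0 follow from the removal itself. The simulations held no variation shared by co-regulated genes. Neither yardstick therefore settles how unusual r = -0.178 and -0.211 are. The ELF-MF cultures may have differed along the axis that separates the sham groups, whether through the field or the handling of the dishes.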

How the results depend on the processing

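Leaving out both ELF-MF arrays with replicate number 1, and restricting to protein-coding genes, were tests chosen only after results had been seen. For ELF-MF, 0 genes passed as analysed, 2 with the stricter filter, 1 with the mean of a gene's probe sets, 1 with only the ELF-MF arrays fitted, 1 without both number-1 ELF-MF arrays, and 0 to 2 with an array left out. For RF-EMF the count was 0 to 1 with an array left out, and for the difference of the effects 0 to 2, with 1 without both number-1 ELF-MF arrays. With an estimated correlation 0 lists passed in any of the 4 comparisons, and with fry 0, 0, 0 and 19. The RF-EMF list count of 1 became 3 under quantile normalization, 2 over all probe sets and 0 to 3 with an array left out, and the count of 7 for the difference became 1 to 8. Genes separated by at least 1.5-fold numbered 67 (ELF-MF) and 57 (RF-EMF) with a pseudocount of 64, 183 and 235 without a filter, 5 and 5 at 2-fold, and 136 to 470 and 249 to 425 with an array left out, where fewer arrays have to be separated. For RF-EMF they numbered 91 under quantile normalization and 88 with the stricter filter. Under median scaling SMC3 under ELF-MF moved from -0.0012 to 0.0494, no more than the all-gene median did, from -0.0226 to 0.0280. Direction reversed for SMC3 under ELF-MF, from -0.0723 to 0.0699 with an array left out, and for HAL9 under ELF-MF, from -0.60 to 0.0210. It also reversed for the RF-EMF ribosomal protein median, from -0.42 to 0.14, and for POT1 in the difference of the effects, from -0.91 to 0.0380. The other genes followed through the alternatives kept their direction, and in the sham comparison they stayed past the threshold (1094 of 1094 values) with 2512 to 2858 genes past it when an array was left out. Apart from the looser criterion, the cause of these changes was not tested.

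Replicate numbers were not shown to pair the cultures. Control probe sets of 2 of 3 kinds nevertheless differed by number in every group, a difference between arrays that the main fit left in its spread. With the number as a block over all 8 arrays, 291 genes (ELF-MF), 326 (RF-EMF) and 265 (difference) had an unadjusted p under 0.05 by limma. The main fit gave 189, 219 and 182. With the number as a block within each exposure system, 1 gene passed for ELF-MF and 2944 for the sham comparison. With the number as a block over all 8 arrays, 2 genes passed for ELF-MF, 1 for RF-EMF, 1 for the difference and 2987 for the sham comparison. With an array left out, a group holds a lone array that is assumed to vary like the other groups. Signal over background, which was not measured here, limits what weakly expressed genes can show. On an array 78.7% to 86.9% of values lay above the pseudocount of 16, a chosen constant rather than a background level.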

Other observations

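In this part, the test of the scaling of the arrays was chosen only after results had been seen. On the 8 arrays the intensity of URA3 was 0.954 to 2.46, that of MET17 1.69 to 33.7 and that of LEU2 4.15 to 50.9, while HIS3 gave 545 to 1197. The labels name S288C with a catalogue number recalled as that of a MATa derivative lacking URA3, MET17 and LEU2 and part of HIS3, and the part of HIS3 that the probe set covers was not examined. The a-cell receptor gene STE2 gave 340 to 1222, against 4.46 to 70.9 for the alpha-cell receptor gene STE3 and 21.3 to 121 for the alpha-factor gene MF(ALPHA)1.

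Single members of further lists differed between the sham groups, while none of the 5 lists named here passed camera with the preset correlation. Relative to the ELF-MF sham arrays, 5 of 26 oxidative stress genes rose and 14 fell (adjusted p = 0.120), and 7 of 15 anaerobic and hypoxic genes rose and 6 fell (adjusted p = 0.181). Of 24 cell wall genes 9 rose and 10 fell (adjusted p = 0.510), and of 32 proteasome genes 13 rose, 2 fell and 17 did not pass (adjusted p = 0.103). Of 8 hexose transporter genes 3 rose and 5 fell (adjusted p = 0.771). By fry the oxidative stress (adjusted p = 0.000231), anaerobic (adjusted p = 0.00211) and hexose transporter (adjusted p = 0.00296) lists passed, and the cell wall (adjusted p = 0.301) and proteasome (adjusted p = 0.441) lists did not. Fry does not compare a list with other genes. Of all tested genes 67.2% passed in this comparison. Among the RNA genes, 66 of 67 tRNA genes and 16 of 31 snoRNA genes passed by limma. Higher on the RF-EMF sham arrays were 55 of the 67 tRNA genes (median 1.30) and 17 of the 31 snoRNA genes (median 0.05).

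The tRNA genes had a median of 0.26 under ELF-MF and -0.63 under RF-EMF, from which a constant difference between replicate numbers cancels, since each group held 1 array of either number. Within the numbers the medians were 0.39 and 0.09 for ELF-MF and -0.78 and -0.40 for RF-EMF. Variation shared by tRNA probe sets may account for the pattern. Camera with an estimated correlation gave p = 0.0281 for the difference of the effects, which met the bound of 0.05 written beforehand to exclude it. That bound ignored that tRNA genes were picked from 12 class and comparison pairs after their values were seen. Multiplied by 12 the p is 0.337, a stricter bar set once the p was known. The correlation came from a fit without the replicate number, although the tRNA median of replicate 2 minus replicate 1 was negative in each group (-0.66 to -0.15). No tRNA test with the number as a block was run, so this test does not decide. A difference in RNA preparation or labelling between the arrays also stays open: under RF-EMF the medians of snoRNA (-0.06), snRNA (-0.37) and rRNA genes (-0.34) lay below the all-gene median of 0.12 too, whereas under ELF-MF those of snoRNA genes (0.17) lay above and those of snRNA (-0.31) and rRNA genes (-0.32) below that of all genes (-0.02). No biological explanation of the tRNA pattern was tested.

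Between the sham groups 2850 genes differed. The scaling of the arrays as the whole source is argued against, since 2853 genes passed under quantile normalization and 2894 under median scaling. A different glucose supply or growth stage stays open and is consistent with the transporters: those made at high glucose, HXT1 (4.55) and HXT3 (2.64), had a median of 3.60, and those made at low glucose, HXT5 (-5.88, with RF-EMF sham intensities of 12.6 and 15.0, so that its size depends on the pseudocount), HXT6 (-2.70) and HXT7 (-2.55), a median of -2.70. That prediction was written before the transporter values were seen but after those of stress and respiratory genes, so it is not independent of them. Whether dish size, time or another step of the experiments set this difference was not tested.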
